A study of Gallus gallus with 4 samples.

How the data were processed

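Micro-C maps which stretches of DNA lie close together in the nucleus, by cutting chromatin with micrococcal nuclease, joining neighbouring ends and sequencing the joined pairs. The libraries came from the dermis of White Leghorn embryos at embryonic day 9, taken from scalp, dorsal and tail skin, and from the feather mesenchyme of juvenile Polish chickens, a crested breed. Each of the 4 groups held 1 library. The sample labels name the Polish tissue as cranial feather mesenchyme, while the design text of the series names crest mesenchyme, so the Polish library is called by its breed here. The genotype label of that library gives a duplication of 195 bp.

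Per the submitters' processing notes, reads were handled with BWA and SAMtools on the chicken build GRCg6a, with no versions given. The loop lists covered chromosome 33 at bins of 5 and 10 kb. The false discovery rate of each loop, a q-value, is printed as the authors deposited it, and the highest q-value in the lists was 0.198. The detection scale is, per the file headers, a score of the loop caller, and it was not used to rank loops. The loop caller is not given in the sources used here. Domains of chromatin contact were called with juicer_tools 1.22.01, per the file headers, at 10 kb bins and without a score. The deposited lists give no read or contact counts, so the depth of each library is unknown and no value could be scaled by it.

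The gene annotation was that of GRCg6a with an insertion of 195 bp at chromosome 33, 7587783 to 7587977. The insertion lies in HOXC10 between its 2 annotated exons, 7585953 to 7586778 and 7589910 to 7590725, outside both untranslated regions. The 2 parts into which the insertion divided HOXC10 were joined. Of 24356 genes, 13512 carried a symbol, and on chromosome 33 this held for 155 of 454. HOXC8, HOXC9 and HOXC10 were the 3 HOXC genes with a symbol, out of 9 symbols in the HoxC list. The HoxC interval ran from the first to the last base of these 3 genes. It may be only part of the cluster, so loops around it may still lie within the cluster. Counts at HoxC refer to this interval. All coordinates are counted from 1. Gene positions are those of GRCg6a with the insertion, so on chromosome 33 those beyond it are 195 bp higher than in GRCg6a itself. The authors named the White Leghorn lists and the Polish domain list for GRCg6a and the Polish loop list for the build with the insertion. Loops were set against these gene positions, and for the White Leghorn libraries also with the genes moved back by 195 bp. A RefSeq gene table of the later build GRCg7b was used only for the order of genes.

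A loop was matched in another library when both anchors, extended by 5 kb on each side, overlapped the anchors of a loop there by at least 1 bp. A loop belonged to HoxC when an anchor touched the HoxC interval. A gene lay at an anchor when its transcription start site (TSS), the first base of the gene on its strand, fell within the anchor extended by 5 kb. Domain starts and ends were taken as boundaries. For the matching between libraries and for gene lists, those 10 kb apart or less were merged into 1 boundary, while at the Hox clusters each start and end is given singly. A boundary was matched when one of the other library lay within 10 kb. Exact Clopper-Pearson 95% intervals are given for shares and order-statistic 95% intervals for medians, and they cover counting error only. All loops of a list were moved together by a random multiple of 5 kb along positions 3720001 to 7745000, with their span kept. The shift was drawn 10000 times, so shifts recur among the draws, and shifts of 5 kb are among those possible. Boundaries were shifted 1000 times along each chromosome. A single dorsal loop set the start of that range, while loops of scalp, tail and the Polish library began at 4940001, 4950001 and 4745001. Placements thus also fell where few loops were called, which can raise the percentiles given for loops. Gene lists were set beside 10000 random lists of the same size, except that no percentile is given for Hox clusters at boundaries, where neighbours share a boundary. These random values describe the libraries and test no difference between regions. With 1 library per group no p-value was computed.

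Gene lists, the rule for named genes and most alternatives were fixed before the data were examined. All HOXC genes with a symbol are named, with HOXA, HOXB and HOXD genes that have a boundary within 10 kb of them or of their cluster. Members of the lists at a loop anchor are named, as are protein-coding genes at the 10 loops of lowest q-value per library. For boundaries the rule takes list members within 10 kb of a boundary in all 3 embryonic libraries or in exactly 1, up to 10 of each in order of symbol. Not every gene that the rule takes is reported here. The alternatives changed the q-value limit, the bin size, the extension of anchors, the number of loops, the HoxC interval, the tolerance for boundaries and the chromosomes used. The matching of loops and boundaries was tested on simulated lists, where all 12 planted loops and all 300 planted boundaries were found. Planted ones lay within the extension or the tolerance, so this checked the code alone. With 12 loops planted 15 were matched, so loops near a planted one can match too. Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1 and Matplotlib 3.10.9 were used.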

Results

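Chromatin contacts were described in 4 Micro-C libraries, to ask how the folding of chromosome 33 relates to the regional use of the HoxC genes. HoxC is a cluster of homeobox genes that set position along the body axis. The libraries were dermis of White Leghorn scalp, dorsal and tail skin at embryonic day 9 and feather mesenchyme of juvenile Polish chickens. Strain, age, tissue and genotype all differed between the Polish library and the others, so it is described apart. There were no replicates, and the depth behind each list is unknown.

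The keratin region carried the loop of lowest q-value in the Polish library and 2 of the 3 loops tied for the lowest in the scalp library. In scalp, KRT18, a keratin of simple epithelia, was joined to BIN2 and CELA1 over 350 kb and to BCDIN3D over 230 kb, each at a q-value of 0.0224. The third of these scalp loops lay around HOXC10, HOXC9 and HOXC8 and joined 7540001 to 7550000 with 7650001 to 7660000. In the Polish library a 10 kb loop from 5170001 to 5180000 reached the KRT18 anchor at a q-value of 0.00377. HNRNPA1, which encodes an RNA-binding protein beside HoxC, lay at the loop of lowest q-value in dorsal (0.000293) and in tail (0.00936). In tail the other anchor of that loop was beside HOXC10.

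Among the 10 loops of lowest q-value, scalp and dorsal both held BCDIN3D and TWIST3, a basic helix-loop-helix transcription factor gene. Scalp also joined RACGAP1 to TWIST3 over 90 kb, the group of PRPH, C1QL4 and DNAJC22 to INHBC over 140 kb, and DNAJC22 and SPATS2 to GPR182 and NACA over 1430 kb. In dorsal, TWIST3 was joined to HOXC10 over 1670 kb (the genes lie 40 ranks apart in GRCg6a and 9 in GRCg7b, among 104 genes ranked in both), and CCS and RBM14 lay at a loop of 315 kb. Tail held BCDIN3D as well. It added EML3 with FAU over 50 kb and SMAGP and BIN2 with KRT18 over 360 kb, both matched in scalp. A tail loop at CDK2 and PMEL was matched in dorsal and the Polish library. Another, of INHBC with PTGES3 and ATP5B over 1320 kb, had no match. The Polish library added KRT6A over 125 kb, without a match. It also joined the group of SPRYD3, MFSD5 and RARG to SP7 and SP1 over 180 kb, matched in scalp and dorsal.

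Loop calls numbered 40 in scalp, 113 in dorsal, 52 in tail and 55 in the Polish library. The median span was 165 kb in scalp (95% interval 110 to 300), 340 kb in dorsal (270 to 470), 157.5 kb in tail (120 to 230) and 150 kb in the Polish library (110 to 220). It was 260, 450, 270 and 220 kb with 10 kb bins alone and 130, 307.5, 110 and 125 kb with 5 kb bins alone. Loops of 1 Mb or more numbered 8, 26, 7 and 7 in the same order. At a q-value of 0.05 or less the lists fell to 6, 32, 11 and 7 loops.

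**Figure D1:**
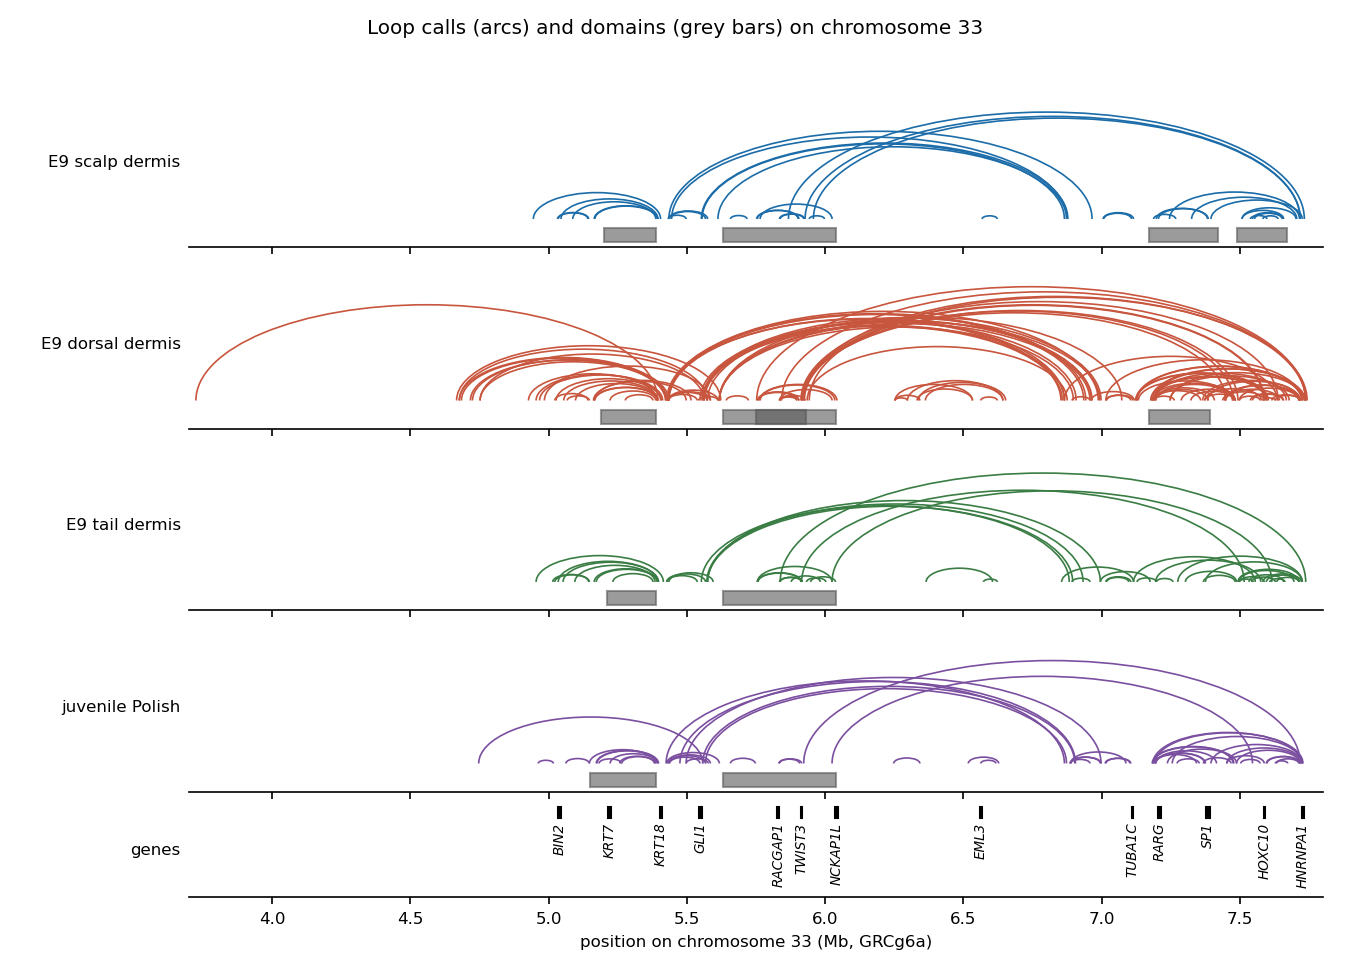
Loops and domains on chromosome 33, with position in Mb on the horizontal axis and 1 track per library. Each arc joins the middles of the anchors of a loop and its height grows with the span, grey bars are domains, and the dorsal track holds the most arcs (113).

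Loops with a match in each of the other libraries lay at the keratins, at INHBC and at the tubulins. The region of BCDIN3D, near 5160001 to 5170000, was joined to that of KRT18 at 5390001 to 5400000 in the 3 embryonic libraries, around KRT80, KRT7, KRT75, KRT6A and KRT5. Its q-values were 0.0224 in scalp, 0.00190 in dorsal and 0.0218 in tail. The Polish loop at the KRT18 anchor was matched in each other library as well. PRPH and C1QL4 were joined to INHBC, a gene of the activin family, over 140 kb in scalp, dorsal and tail and 135 kb in the Polish library. TUBA1C, a tubulin gene, lay at a loop of 90 kb in dorsal, tail and the Polish library and of 100 and 110 kb in scalp. RACGAP1 was joined to TWIST3 by loops of scalp (q-value 0.0324), tail (q-value 0.153) and the Polish library (q-value 0.0611) that each had a match in all other libraries. The same held for a scalp loop of EML3 with FAU (q-value 0.133). Of the loops of each library, 8 in scalp, 5 in dorsal, 5 in tail and 7 in the Polish library were matched in all others, while 14, 69, 24 and 24 were matched in none.

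Among the embryonic libraries, 21 of 40 scalp loops were matched in dorsal (52.5%, 36.1 to 68.5), 14 of 40 scalp loops in tail (35%, 20.6 to 51.7) and 23 of 52 tail loops in dorsal (44.2%, 30.5 to 58.7). The Polish library had 26 of its 55 loops matched in dorsal (47.3%, 33.7 to 61.2). It matched 14 of 40 scalp loops (35%, 20.6 to 51.7) and 12 of 52 tail loops (23.1%, 12.5 to 36.8). Random placement gave a median of 0% for each of these pairs and at most 7.5% at the 97.5 percentile. From the longer list, dorsal loops were matched at 16.8% in scalp, 19.5% in tail and 22.1% in the Polish library, tail loops at 28.8% in scalp, and Polish loops at 21.8% in scalp and 23.6% in tail. The dorsal list was the longest, and when it was trimmed to its loops of lowest q-value at the length of the other list, the match of scalp was 25%, that of tail 25% and that of the Polish library 40%. Without extended anchors the 6 shares lay between 2.5% and 22.5%.

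The series asks how contacts at HoxC relate to its regional expression. In dorsal, HOXC10 was joined to TWIST3 by loops of 5 kb bins (5915001 to 5920000 with 7585001 to 7590000, q-value 0.00231) and of 10 kb bins (q-value 0.00776). The dorsal anchor at HOXC9 was joined to TUBA1A and TUBA1B over 480 kb (q-value 0.0209), and HOXC8 to HNRNPA1 over 100 kb (q-value 0.00318). In tail and in the Polish library an anchor at HOXC10 and HOXC9, 7590001 to 7600000, was joined to HNRNPA1 at 7710001 to 7720000, with q-values of 0.0218 and 0.0295. No scalp loop joined a named HOXC gene to HNRNPA1, and the scalp loop in HoxC joined HOXC9 to 7535001 to 7540000 over 60 kb (q-value 0.0910). The scalp loop from 7540001 to 7660000 had its anchors on either side of HOXC10, HOXC9 and HOXC8, with no TSS of a named gene at them. It was matched in dorsal (q-value 0.0862 there), where a loop with the same anchors was called. A further dorsal loop around the genes, 7535001 to 7540000 with 7655001 to 7660000 (q-value 0.0272), was matched in scalp and in tail. In tail a loop of 7530001 to 7535000 with 7655001 to 7660000 enclosed the genes too (q-value 0.0137).

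HoxC loops numbered 1 of 40 in scalp (2.5%, 0.0633 to 13.2), 8 of 113 in dorsal (7.08%, 3.11 to 13.5), 4 of 52 in tail (7.69%, 2.14 to 18.5) and 3 of 55 in the Polish library (5.45%, 1.14 to 15.1). No difference between the libraries was tested, and the counts include contacts called at both bin sizes. No loop had both anchors inside the HoxC interval, and none of the 8 dorsal loops was matched in another library. Both hold for the interval of the 3 named genes, not for the whole cluster. The dorsal loop of lowest q-value (0.000293) joined 7625001 to 7630000, just beyond HOXC8, to HNRNPA1. It was matched in tail and in the Polish library. For the loops counted at HoxC the partner lay beyond HOXC8 for 0, 1, 2 and 2 loops and beyond HOXC10 for 1, 7, 2 and 1. Compared with random placements, the numbers of HoxC loops stood at percentiles 73.7, 98.1, 96.9 and 93.3, which the sparse start of the placement range can raise. HOXC10 (7585953 to 7590725) lay at 1, 6, 3 and 2 loops, HOXC9 (7601517 to 7604373) at 1, 4, 2 and 2, and HOXC8 (7605941 to 7616791) at 0, 2, 2 and 0. The bin with the insertion site in HOXC10, 7585001 to 7590000, was an anchor in the Polish library (to 7450001, q-value 0.178), in tail (to 7495001, q-value 0.109) and in dorsal (to TWIST3 and, at a q-value of 0.168, to 7435001). With dorsal trimmed to 40 loops its HoxC loops numbered 5, and an interval wider by 20 kb on each side gave 2, 14, 8 and 6 and one wider by 50 kb gave 5, 18, 11 and 7. Loops with an anchor on each side of HoxC and none in it, counted after the data were seen, numbered 11, 23, 8 and 7, of which 8, 18, 7 and 6 spanned less than 1 Mb.

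**Figure D2:**
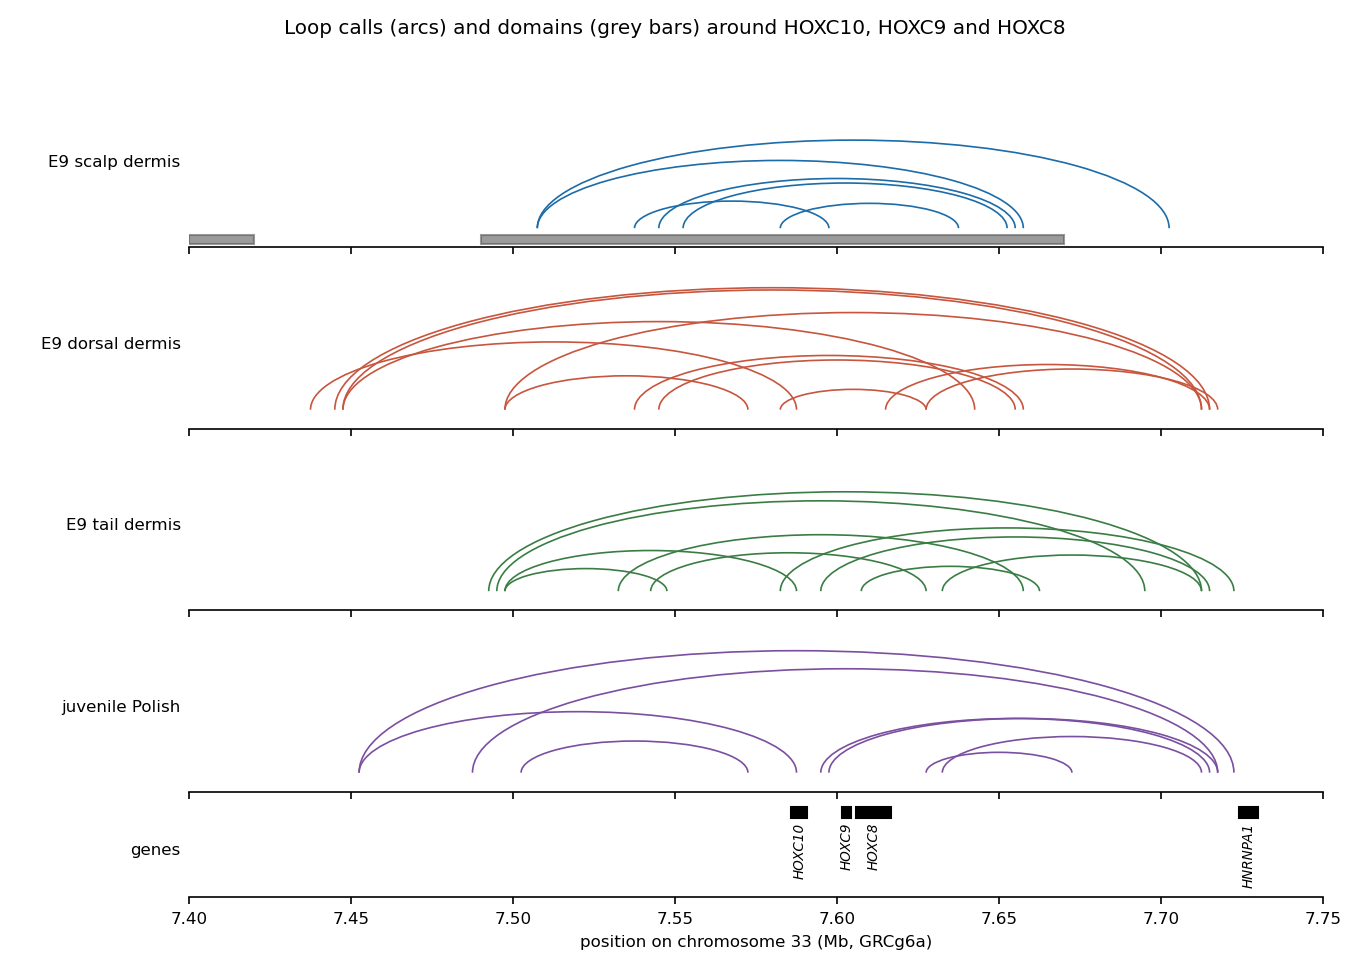
Loops and domains around HOXC10, HOXC9 and HOXC8 on chromosome 33, with position in Mb on the horizontal axis and 1 track per library. Arcs join the middles of anchors that both lie in the plotted range and grey bars are domains. Arcs from the HOXC genes to HNRNPA1 stand in dorsal, tail and the Polish library, and the scalp track has a domain over these genes.

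Of the 3 signalling genes on the chromosome, RARG, a retinoic acid receptor gene, and GLI1, a transcription factor gene of hedgehog signalling, were at an anchor in all 4 libraries, and WNT1 in none. WNT1 (3422447 to 3427906) lies before the first loop of any library and outside the range of placements, so neither could reach it. This count of 2, the highest that placements could give, stood at percentiles 96.2, 87.5, 94.5 and 95.1 of random placements in scalp, dorsal, tail and the Polish library. At a q-value of 0.05 or less it was 0, 0, 0 and 1. Keratins at anchors numbered 1 of 6 in scalp (KRT18), 2 in dorsal (KRT7, KRT18), 1 in tail (KRT18) and 4 in the Polish library (KRT5, KRT6A, KRT7, KRT18), at percentiles 42, 24.2, 30.3 and 91.2 of random placements. Without extended anchors these counts were 1, 1, 0 and 1. KRT6A in the Polish library was joined to 5380001 to 5385000 at a q-value of 0.0130.

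Genes known to lie beside HoxC in vertebrates were at anchors for 9, 11, 9 and 10 of 15 members in scalp, dorsal, tail and the Polish library, at percentiles 96.7, 88.2, 90.8 and 97.1. These counts were 0, 4, 2 and 7 at a q-value of 0.1 or less and 6, 7, 4 and 5 without extended anchors. HNRNPA1, SP1, RARG, SPRYD3, TNS2 and MFSD5 were at anchors in all 4. NCKAP1L was at one in dorsal, ITGB7 in scalp and ESPL1 in the Polish library, and SP7 and AAAS were at anchors in all but scalp. EIF4B was at one in all but the Polish library and PFDN5 in all but tail. Of the widely expressed control genes, the tubulins TUBA1A, TUBA1B and TUBA1C gave 2, 3, 3 and 1 of 3, at percentiles 83.1, 87.7, 93.0 and 63.7. HOXC8, HOXC9 and HOXC10 gave 2, 3, 3 and 2 of 3, at percentiles 88.2, 90.7, 95.6 and 84.0. All protein-coding genes at anchors numbered 71, 131, 93 and 92 of 361. The 361 include genes before the first loop of any library, which no anchor could reach. This share is thus no like background for the lists. Of the 29 list members on the chromosome, 15, 20, 17 and 18 were at anchors, and 1, 10, 4 and 10 at a q-value of 0.05 or less.

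Domains on chromosome 33 framed the keratins and the genes from ATF1 to NEUROD4. A domain with KRT7, KRT75, KRT6A and KRT5 ended at 5390000 in all 4 libraries and began at 5200001 in scalp, 5190001 in dorsal, 5210001 in tail and 5150001 in the Polish library. A domain at 5630001 to 6040000, which holds RACGAP1, HDAC7 and TWIST3, was called in all 4 libraries with the same ends. Scalp and dorsal had a domain from 7170001 that holds TNS2, RARG, COL2A1, VDR, SP7 and SP1. The domain 7490001 to 7670000, which holds HOXC10, HOXC9 and HOXC8, was called in scalp. No domain of dorsal, tail or the Polish library overlapped it, which held for 113 of all 1854 scalp domains (6.09%, 5.05 to 7.28). Tail and the Polish library had no domain on the chromosome beyond 6040000.

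Over the genome, 1854 domains were called in scalp, 998 in dorsal, 1937 in tail and 207 in the Polish library, which covered 626.7, 298.9, 671.5 and 66.3 Mb. The median size was 260 kb in scalp (260 to 280), 220 kb in dorsal (210 to 220), 300 kb in tail (280 to 310) and 200 kb in the Polish library (190 to 230). Chromosomes 1 to 5 and Z held 62.1% of scalp domains (59.9 to 64.4) and 61.6% of tail domains (59.4 to 63.8), against 39.2% in dorsal (36.1 to 42.3) and 27.5% in the Polish library (21.6 to 34.2).

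Boundary matches are given first from the shorter list of each pair. Of scalp boundaries 2311 of 3448 were matched in tail (67.0%, 65.4 to 68.6), and of dorsal boundaries 1170 of 1860 in scalp (62.9%, 60.7 to 65.1) and 1202 of 1864 in tail (64.5%, 62.3 to 66.7). The Polish library had 55.9% of its 408 boundaries matched in scalp (50.9 to 60.8), 60.0% in dorsal (55.1 to 64.8) and 55.4% in tail (50.4 to 60.3). Shifted boundaries gave medians from 7.60% to 9.84% for these shares. From the longer list, 64.8% of tail boundaries were matched in scalp, 34.3% of scalp and 34.0% of tail boundaries in dorsal, and 6.70% of scalp, 13.4% of dorsal and 6.47% of tail boundaries in the Polish library. With no tolerance the 6 shares lay between 25.5% and 36.0%.

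Domains over HoxA, a cluster like HoxC, had ends that differed between the embryonic libraries, though dorsal and tail shared a matched boundary. In scalp 1 domain, 32570001 to 32710000 on chromosome 2, covered the whole HoxA cluster. In dorsal a domain ended inside it at 32620000, 4.95 kb from the TSS of HOXA5 and within 10 kb of HOXA3, HOXA4 and HOXA6. In tail domains ended at 32630000 and 32640000, near HOXA6 and HOXA7 and within 10 kb of HOXA9. Another tail domain began at 32670001, 3.91 kb from HOXA11. The tail end at 32630000 lay within 10 kb of the dorsal one and so matched it. HOXA3, HOXA5 and HOXA6 were near a boundary in both dorsal and tail. The Polish library had no domain over HoxA. Of 14807 windows of this length on the chromosome, 1.20% had no boundary in scalp and at least 1 in dorsal and in tail, an arrangement taken from HoxA itself.

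HoxB on chromosome 27 lay whole inside a domain in all 4 libraries, of 320 kb in scalp, 350 kb in dorsal, 330 kb in tail and 290 kb in the Polish library. Scalp had a further boundary at 6280000 beside HOXB2 and HOXB1, and the Polish domain began at 6150001 beside HOXB13. HoxD on chromosome 7 had a boundary at 16300000, 0.799 kb from the TSS of HOXD9, in all 4 libraries, with HOXD8 and HOXD10 within 10 kb of it. Scalp and tail had a further boundary at 16290000, 2.89 kb from the TSS of HOXD8, and dorsal had one at 16330000, beside HOXD13 and HOXD12.

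**Figure D3:**
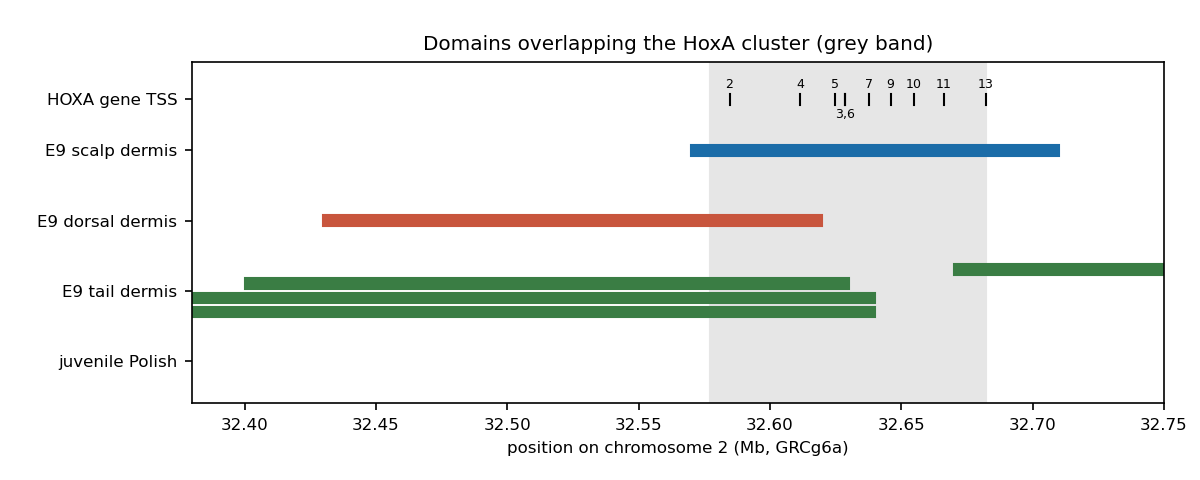
Domains that overlap the HoxA cluster on chromosome 2, with position in Mb on the horizontal axis and 1 line per library, bars for domains (ended at the edge where they reach past it), ticks for TSSs of the numbered HOXA genes and a grey band for the cluster. The scalp bar covers the band, the dorsal bar ends at 32620000 and tail bars end at 32630000 and 32640000.

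Of the genes in the fixed lists, CYP26B1, which encodes an enzyme that degrades retinoic acid, FOXC2, SFRP1, WNT3A, NCKAP1L, HOXD8, HOXD9 and HOXD10 lay within 10 kb of a boundary in all 3 embryonic libraries. Among those near a boundary in exactly 1 of them, CHRD, DKK3, FGF8, GBX2 and GLI2 were near one in scalp, B2M and CTNNB1 in dorsal, and ALX4, CDX2 and DLX6 in tail. Patterning transcription factors near a boundary numbered 13 of 57 in scalp, 3 in dorsal, 13 in tail and 1 in the Polish library, at percentiles 93.5, 7.14, 91.0 and 41.0 of random lists. Within 20 kb they numbered 22, 7, 21 and 4, and within 50 kb 32, 19, 31 and 5. Signalling genes numbered 12, 6, 8 and 2 of 54, at percentiles 91.6, 51.4, 40.8 and 72.5, and within 50 kb 24, 16, 27 and 6.

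The HoxA list had 1, 4, 6 and 0 of 11 members near a boundary in scalp, dorsal, tail and the Polish library. The HoxD list had 3, 5, 3 and 3 of 8. Within 50 kb the HoxA list had 5, 10, 10 and 0 and the HoxD list 8 in each library. Neighbours in a cluster shared boundaries, so that the dorsal boundary at 32620000 alone took in HOXA3, HOXA4, HOXA5 and HOXA6, and the Polish boundary at 16300000 took in HOXD8, HOXD9 and HOXD10. HoxB had 2, 0, 0 and 1 of 10 (5, 1, 1 and 2 within 50 kb) and HoxC 0 of 3 in each library at both distances. The genes beside HoxC had 1 of 15 in each, but 8, 10, 2 and 2 within 50 kb. Type II and related keratins had 1, 0, 2 and 0 of 6, and 4, 3, 5 and 1 within 50 kb, and type I keratins 0 of 7 in each, and 2 in each within 50 kb. Chromatin architecture genes had 2, 0, 1 and 2 of 11 (percentiles 62.3, 13.1, 29.2 and 98.5), with CTCF and MAU2 near a boundary in the Polish library, and control genes 3, 3, 6 and 0 of 24 (percentiles 37.5, 60.1, 87.4 and 27.4). Within 50 kb the chromatin architecture genes had 7, 5, 8 and 3 and the control genes 13, 10, 14 and 2. All named protein-coding genes near a boundary made up 15.3% in scalp, 11.2% in dorsal, 16.1% in tail and 2.47% in the Polish library.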

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

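Alternatives that counted loops found at both bin sizes once, left out loops of 1 Mb or more, widened the HoxC interval by 50 kb, took loops around that interval or moved genes back by the insertion were chosen after seeing the data, and the others before. Orders below are scalp, dorsal, tail and Polish unless said otherwise, and where no reason is given the cause was not tested. No paired analysis was possible because each group held 1 library. Domains of 100 kb or more were all domains, so that alternative removed nothing, and depth is unknown, so its effect could not be measured.

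A lower q-value limit or a single bin size removes loops by construction. At 0.1 there were 16, 56, 24 and 18 loops, the scalp match in dorsal was 68.8%, HoxC loops in tail were 1, HOXC genes at scalp anchors were 1, and list members at anchors were 4, 12 and 7 in the embryonic libraries. At 0.05 there were 6, 32, 11 and 7 loops, the scalp match in dorsal was 83.3%, HoxC loops were 0, 5 and 1 in the embryonic libraries, HOXC genes at scalp anchors were 0, and list members were 1, 10, 4 and 10. Bins of 10 kb alone gave 17, 33, 23 and 16 loops, 0, 4, 2 and 1 HoxC loops and 0 HOXC genes at scalp anchors. Bins of 5 kb alone gave 23 loops in scalp and 29 in tail, 4 HoxC loops in dorsal and 2 in tail. The scalp match was then 26.1% in dorsal and 17.4% in tail, and the Polish match in dorsal 30.8%.

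With as many loops in both lists, the match in dorsal was 25% for scalp and 25% for tail, and dorsal had 5 HoxC loops. Without extended anchors scalp loops were matched at 22.5% in dorsal, 5% in tail and 2.5% in the Polish library, tail loops at 7.69% in dorsal and 11.5% in the Polish library, and Polish loops at 7.27% in dorsal. HOXC genes at anchors were then 0 in scalp and 1 in the Polish library, and list members 10 in tail and 7 in the Polish library. Anchors extended by 10 kb gave scalp matches of 70% in dorsal and 55% in tail, and HoxC loops of 2 in scalp and 7 in tail, and an extension by 5 kb gave 2 HoxC loops in scalp. A HoxC interval wider by 20 kb gave 2, 14, 8 and 6 loops and one wider by 50 kb gave 5, 18, 11 and 7, with scalp lowest in both. Loops with an anchor on each side of the interval numbered 11, 23, 8 and 7, with scalp above tail and Polish. Moving genes back by the insertion changed no count of HoxC loops or of list members at anchors in the embryonic libraries.

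Chromosomes 1 to 5 and Z alone held 1152, 391, 1194 and 57 domains, a median size in tail of 320 kb, and 18, 10, 24 and 1 list members at boundaries. On them scalp boundaries were matched in tail at 64.6%, dorsal ones in tail at 61.7% and Polish ones in dorsal at 55.0%. Boundary shares are given for dorsal in scalp, dorsal in tail, scalp in tail, and Polish in scalp, dorsal and tail. They were 33.8%, 34.1%, 36.0%, 25.5%, 29.9% and 26.2% with no tolerance. A tolerance of 20 kb gave 73.4%, 74.6%, 78.2%, 70.3%, 74.0% and 70.3%, and 50 kb gave 85.4%, 86.5%, 87.7%, 87.7%, 88.0% and 88.2%. List members within 20 kb of a boundary were 40 in dorsal, 66 in tail and 17 in the Polish library, and within 50 kb 107, 83, 108 and 31. Boundaries within 50 kb of the 4 Hox clusters numbered 8 in scalp and 8 in tail.

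Of the alternatives for these values 108 moved, as given above, and 191 stayed within 1.5 times the count or within the 95% interval. Of those for single gene lists, single Hox clusters and loop spans, 244 did so and 136 did not. Counts of list members at anchors were equal in 86 of these, lower in 57 and higher in 13, and those at boundaries equal in 84, lower in 24 and higher in 68. Boundaries at single Hox clusters were equal in 13 and higher in 11, and the median span was equal in 2, lower in 13 and higher in 9. The 191 include alternatives that could hardly move a value, such as domains of 100 kb or more and chromosomes with calls in all 4 libraries. Their number is thus no measure of stability.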

Other observations

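The tests of long loops were chosen after the loops were seen, and those of the HoxC and HoxA domains were set before their results were seen, though the patterns themselves were picked from the data. GLI1 lay at an anchor of a loop of more than 1 Mb in each library. In scalp a loop to NACA spanned 1325 kb (q-value 0.0830), and in tail a loop to NACA and PTGES3 spanned 1330 kb (q-value 0.0716). In dorsal a loop to ZBTB39 and GPR182 spanned 1310 kb (q-value 0.121), and scalp had a loop with the same anchors (q-value 0.142). Dorsal had further such loops of GLI1 over 1360 kb (q-value 0.171) and 1440 kb (q-value 0.154). In the Polish library the partner of the 1345 kb loop (q-value 0.130) held no TSS of a named protein-coding gene. These loops of GLI1 were chosen after their values were seen, and such loops were not particular to GLI1. Loops of more than 1 Mb also lay at PRPH in scalp, dorsal and the Polish library. At INHBC they lay in dorsal, tail and the Polish library.

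Loops of 1 Mb or more numbered 48 over the 4 libraries, among them TWIST3 with HOXC10 in dorsal. Of these, 12 were matched in another library, against 3 at the 97.5 percentile of random placements. A contact matched between libraries counts in each of them, while placements moved each list against the unmoved others, so that percentile may be too low. The matches speak for the matched loops alone. Long loops of all 4 libraries joined 5420001 to 5620000 with 6850001 to 7075000 or 5750001 to 6030000 with 7445001 to 7745000. The exception was a dorsal loop from 3720001. These stretches, noticed afterwards and not set beside placements, argue against calls without signal for long loops as a set. For each single loop without a match calls without signal stay open, among them TWIST3 with HOXC10. A candidate explanation is that segments of chromosome 33 stand in another order in GRCg7b, where TWIST3 and HOXC10 lie 9 ranks apart among 104 shared genes, against 40 in GRCg6a. NCKAP1L and HNRNPA1, from the list of genes beside HoxC, lie 1 rank apart in GRCg7b, against 38 in GRCg6a. Both tests of this explanation left it open. Anchor genes were closer in GRCg7b for 91.7% of the 36 loops with a gene at both anchors, but the median of random placements was 89.5%. Their 97.5 percentile was 100%, which no share can exceed, so the first test could not have favoured the explanation. The second test, run after that result, gave a median distance of 8.5 ranks, against 28 in GRCg6a. This stood at percentile 4.71 of placements, with 7 at their 2.5 percentile and 26 at their median. Loops under 1 Mb had a median of 7 ranks in both builds, and 5 of 128 were closer in GRCg7b. No biological explanation was tested.

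The domain over HOXC10, HOXC9 and HOXC8 was called in scalp and in no other library. Tail and the Polish library had no domain on chromosome 33 beyond 6040000, so the absence there was not particular to HoxC. Of all scalp domains, 43.6% had no counterpart with both ends within 10 kb in any other library, a share that shifted ends and regional differences raise as well, so it decides nothing about variable calling. Domains that none of another library overlapped, as at HoxC, made up 6.09% (113 of 1854), a value added after the others were seen. Variable calling and a difference between skin regions both stay open, since each region had 1 library.

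The HoxA cluster lay whole in 1 scalp domain and was divided in dorsal and in tail. The dorsal end near HOXA5 and a tail end near HOXA6 lay within 10 kb of each other and count as matched. Tail was also divided near HOXA7 and HOXA11. On chromosome 2, 1.20% of windows of the length of HoxA had no boundary in scalp and at least 1 in dorsal and in tail. This arrangement was defined from HoxA itself, so a low share excludes nothing. HoxA was 1 of 4 clusters looked at, and variable calling at this cluster stays open. A regional difference in the fold of HoxA remains a hypothesis that replicate libraries could test.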
